A study of Mus musculus with 6 samples.

How the data were processed

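Polyadenylated RNA was sequenced from mouse small intestinal enteroids, which are epithelial cultures grown from crypts in Matrigel, per the labels' protocols. The mice were C57BL/6, the medium was serum-free ENR, and RNA was taken up in Trizol and cleaned on RNeasy columns. Lines had been transfected with piggyBac transposons, which integrate into the genome, for constitutive expression of either GFP or PLAGL2, a zinc finger transcription factor. There were 6 libraries, 2 from a GFP line, 2 from PLAGL2 clone 1, which the labels give a low PLAGL2 level, and 2 from PLAGL2 clone 3, which they give a high level. Replicate A of each line came from passage 5 and replicate B from passage 7. Both libraries of a line therefore come from a single transfected culture. For comparisons of single lines, p-values measure the spread between passages within the lines, not between independent transfections. For both clones against GFP the spread also holds the difference between the clones, with a single GFP line. For passage it is the spread of the passage change between lines.

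The authors deposited a table of RPKM values per gene and a table of RPKM values per transcript, each with 1 value per library. The build was mm10, and the tools named were STAR, Subread, featureCounts and edgeR, per the submitters' processing notes. The roles, order and versions of these tools, any filter, and the way reads were shared between isoforms are not given in the sources used here. The gene table listed 41383 entries for 40769 identifiers, and the 614 repeated entries were dropped. The transcript table listed 86210 entries for 84653 identifiers, and 1557 were dropped. All value columns of both tables matched 1 library each.

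Depth was recovered from the smallest steps of the RPKM values. With gene lengths of the GENCODE M21 annotation, which held 98.74% of the gene identifiers, 67.7% of the 25468 genes with a nonzero value came out as whole reads within 0.02 of a read in all libraries, and a further 32.2% did so with a length fitted to their own values. The recovered totals were 16604306 and 13779306 reads for GFP at passages 5 and 7, 17319950 and 15433637 for clone 1, and 16664406 and 15078072 for clone 3. A listed 0 allows up to 3 reads, which for a gene of 1 kb is an RPKM of 0.173 to 0.218. This floor covers counting error only. The mitochondrially encoded share of the summed RPKM was 10.83%, 11.18% and 10.67% at passage 5 and 13.03%, 12.58% and 12.17% at passage 7, in GFP, clone 1 and clone 3.

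Because the values were RPKM and not counts, no count test was used as the main test. Values were analysed as log2(RPKM + 0.5) with limma-trend, two-sided, over the 16314 genes and 44747 transcripts with an RPKM of at least 0.5 in at least 2 of the 6 libraries. Benjamini-Hochberg adjustment was applied over all features of a contrast, with a threshold of 0.05. All log2 changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. PLAGL2 against GFP compared the 4 libraries of both clones with the 2 GFP libraries in a fit with 4 residual degrees of freedom, so that the difference between the clones stayed in the spread. Each clone against GFP and clone 3 against clone 1 came from a fit of 3 groups with 3 residual degrees of freedom. Passage 7 against passage 5 came from the same 3 groups with passage as a further term.

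For gene lists, limma's camera with a preset correlation of 0.01 compared the members of each of 22 lists with all other genes, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera rests on the residual degrees of freedom of the fit, 2 to 4 here, and so has little power. A list lost with it is not thereby shown to hold members that move together. Fry tests whether the members move, on balance, one way and does not compare them with other genes. Beside each list that passed in the main fit of a contrast of lines stand the count of members past the threshold over all genes and the count adjusted over the list alone. Between passages only the count over all genes is given. The lists were intestinal stem cell, Wnt target, Wnt ligand and receptor, PLAG family reported target, let-7 target and oncofetal, fetal-like and YAP target, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, enterocyte, cell cycle, Notch pathway, interferon response, p53 target, cholesterol synthesis, antimicrobial and immune epithelial, gastric and colonic identity, proximal-distal small intestine, non-epithelial contaminant, mitochondrially encoded, and replication-dependent histone. Symbols matched 501 listed members to the table and left 1 unmatched.

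The tests, the 22 lists, the rule for named genes and the settings varied were fixed before the data were examined, except where a setting is said to have been chosen later. Named genes were Plagl2, then the largest rises and falls among genes past the threshold with a mean RPKM of at least 2 in one arm and no overlap between the arms' libraries, 12 each way for PLAGL2 against GFP, 6 for each other contrast of lines and 3 for passage. For passage, the same direction in all 3 lines was required in place of no overlap. From each list up to 4 called members with the smallest p were named, or the 2 with the smallest p, as values, where none was called. Unnamed gene models were skipped, and Lgr5, Ascl2, Olfm4, Lyz1, Muc2, Chga, Dclk1, Alpi and Mki67 were always given.

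The replicate letters pair the libraries by passage. Deviations from the line means of libraries with the same letter correlated at 0.32, 0.28 and 0.28 over the pairs of lines, so the letters were taken as a pairing, and a fit with the letter as a block was run as an alternative. Values from it stand beside a result where they change the call or move a count by over 1.5 times. For lists that did not pass, not all such counts are given. The libraries of a line differed by far more than sampling noise, with chi-square values per degree of freedom of 20.3, 23.7 and 25.6, so none was counted as a repeat of another.

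Other alternatives were pseudocounts of 0.1 and 1, no filter or an RPKM of at least 1, median ratio scaling, quantile normalization, robust moderation, fits on the libraries of the compared groups alone, and leaving out each library in turn. Leaving out a library also takes 1 residual degree of freedom from the fit, so a call lost there need not rest on that library. Limma's voom on the recovered reads, thinning of reads to the smallest library and a correction for GC content were added after seeing the data. The fits were tested on simulated data in which 200 of 16314 genes were changed, over 5 draws. At log2 changes of 1, 2 and 4, PLAGL2 against GFP recovered 60.6%, 90.7% and 98.5% of them with 7.8 false calls on average, and clone 3 against GFP recovered 50.1%, 89.3% and 98.8% with 8.2. The corresponding shares were 49.6%, 87.8% and 99.4% with 9.2 false calls for clone 1 against GFP, 51.3%, 85.4% and 99.1% with 9.4 for clone 3 against clone 1, and 79.4%, 95.5% and 99.7% with 13.4 for passage. These shares apply to 200 changed genes. In the data, Nes and Cyp2w1 were called higher in each clone but not in PLAGL2 against GFP, where the difference between the clones stays in the spread. The shares may thus overstate recovery in that fit. Positions are those of the GENCODE annotation of GRCm38, the same assembly as mm10. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.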

Results

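Gene expression was measured in jejunum enteroids from mice to ask which genes differ when PLAGL2, a zinc finger transcription factor of the PLAG family, is over-expressed. The 6 libraries came from a GFP control line, a PLAGL2 line with a low level by its label (clone 1) and a PLAGL2 line with a high level by its label (clone 3), each sampled at passages 5 and 7. There were thus 2 libraries per line, 4 with PLAGL2 and 2 with GFP. Recovered library totals lay between 13779306 and 17319950 reads. Values are RPKM as mean ± SD, and log2 changes are given with their standard errors (SE) from limma-trend, with Benjamini-Hochberg adjusted p.

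Plagl2 (ENSMUSG00000051413, chromosome 2, 153227759 to 153241426, mm10) had an RPKM of 22.9 ± 0.200 in GFP, 28.7 ± 3.10 in clone 1 and 37.2 ± 0.0294 in clone 3 (SD, n = 2 each), in the order of the labels. Its log2 change against GFP was 0.31 (SE 0.10, adjusted p = 0.995) in clone 1 and 0.68 (SE 0.10, adjusted p = 0.0793) in clone 3. The clone 3 value passed the threshold with the replicate block at adjusted p = 0.0358, within a range of 0.000652 to 0.415 over the alternatives. Over both clones the log2 change was 0.50 (SE 0.15, adjusted p = 0.655), and between the clones it was 0.37 (SE 0.10, adjusted p = 0.535). The species and the untranslated regions of the introduced Plagl2 are not given in the sources used here, so these values count only reads that were assigned to the mouse gene.

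Across both clones against GFP, the difference that passed the threshold was that of Mmp14, whose transcripts were nearly absent from both clones. Mmp14 (ENSMUSG00000000957, chromosome 14, 54431612 to 54445364), which encodes a membrane-anchored matrix metalloproteinase, was at an RPKM of 8.37 ± 0.528 in GFP (SD, n = 2) and 0.0830 ± 0.0645 with PLAGL2 (SD, n = 4), a log2 change of -3.93 (SE 0.18, adjusted p = 0.00389). With 1 GFP line and no untransfected line, a gain in the GFP line cannot be told from a loss in both clones. It was lower in all 4 PLAGL2 libraries, which held 7, 4, 0 and 3 of its reads against 345 and 313 in GFP. Among the largest changes that did not pass was that of Reg1, a secreted regenerating family lectin, at 17.3 ± 0.462 in GFP and 153 ± 73.4 with PLAGL2 (log2 change 2.93, SE 0.54, adjusted p = 0.328, range over the alternatives 0.014 to 0.996, the lowest without clone 3 at passage 5). Clca1, a protein of goblet cell mucus, was at 27.7 ± 15 and 2.92 ± 2.36 (log2 change -3.19, SE 0.65, adjusted p = 0.404, range over the alternatives 0.0344 to 0.996). The stem cell genes Lgr5, a receptor that marks crypt base columnar cells, and Ascl2, a transcription factor of the same cells, were at 33.5 ± 11 and 10.9 ± 4.72 in GFP and at 52.2 ± 17.4 and 21.9 ± 11 with PLAGL2, with adjusted p of 0.89 and 0.866. In all, limma-trend called 0 genes higher and 1 lower, with 592 higher and 378 lower at an unadjusted p under 0.05, where chance alone gives 816 of 16314. This does not mean that no gene rose in both clones. Nes was at means of 0.225 in GFP, 5.57 in clone 1 and 14.1 in clone 3, and Cyp2w1 at 1.29, 9.25 and 44.0. Both were called higher in each clone, but the difference between the clones stays in the spread of this fit. Voom on recovered reads, added after seeing the data, called 2 higher and 6 lower. The replicate block gave 0 higher and 2 lower genes, Mmp14 and Reg3g. Reg3g is an antimicrobial lectin, chosen after its values were seen (24.1 ± 7.62 and 10.5 ± 3.57, adjusted p = 0.0439 with the block and 0.625 without it). Mmp14 stayed past the threshold without any 1 PLAGL2 library but not with a pseudocount of 0.1 (adjusted p = 0.0764, in a range of 0.00135 to 0.0764 over the alternatives). Without GFP at passage 5 or GFP at passage 7 Mmp14 no longer met the expression filter, so the count was 0, and without clone 3 at passage 5 it was 3.

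Among gene lists in the same comparison, goblet cell genes were lower as a group and reported targets of PLAG family factors higher. Goblet cells secrete the mucus of the intestine, and 19 of the 20 tested goblet genes were lower with PLAGL2, with a median log2 change of -0.63 (camera adjusted p = 5.92e-15, adjusted p = 0.532 with an estimated correlation). Of these genes 0 passed over all genes and 7 were lower when adjusted over the list alone. Of the 14 tested PLAG family targets 13 were higher, with a median of 0.65 (adjusted p = 6.83e-08, adjusted p = 0.446 with an estimated correlation). Among these were Btc, an EGF receptor ligand, at 4.24 ± 0.0719 and 7.13 ± 0.824, and Cdkn1c, a cell cycle inhibitor, at 2.94 ± 0.146 and 6.21 ± 2.18, of which neither passed on its own. Ascl2 was put on this list from what is known of the present study, so its direction is not independent evidence. Of these targets 0 passed over all genes, and 1 was higher when adjusted over the list alone (3 with the replicate block).

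A further 6 lists passed with the preset correlation and not with an estimated one. The Notch pathway list had a median of 0.20 (adjusted p = 0.00422, adjusted p = 0.711 with an estimated correlation) and Wnt ligands and receptors one of 0.35 (adjusted p = 0.00611, adjusted p = 0.557 with an estimated correlation). The antimicrobial list had a median of -0.30 (adjusted p = 0.0064, adjusted p = 0.532 with an estimated correlation), although Reg1 on it was higher. For Wnt targets the median was 0.17 (adjusted p = 0.0117, adjusted p = 0.854 with an estimated correlation), for proximal-distal genes 0.13 (adjusted p = 0.0134, adjusted p = 0.446 with an estimated correlation) and for let-7 targets 0.07 (adjusted p = 0.0439, adjusted p = 0.532 with an estimated correlation). The let-7 list holds Plagl2, the introduced gene, and without it the list did not pass (median 0.06, adjusted p = 0.122, a test added after seeing the data). Of the members of these lists 0 passed over all genes, and adjusted over the list alone 1 antimicrobial gene was higher and 4 were lower, 1 proximal-distal gene was higher and 0 of the Notch, Wnt or let-7 genes passed. With the replicate block 1 antimicrobial gene was lower over all genes, and over the list alone 2 Notch genes, 4 Wnt targets and 4 Wnt ligand and receptor genes were higher and 1 of the latter was lower. The let-7 list was lost with the replicate block (adjusted p = 0.0916), while the stem cell list (0.0132) and the tuft cell list (0.0395) passed, against 0.149 for both without it, but not with an estimated correlation (0.476 and 0.539). Without GFP at passage 5 the adjusted p was 0.112 for Wnt ligands and receptors, 0.117 for the antimicrobial list, 0.579 for Wnt targets and 0.183 for let-7 targets. Wnt targets were also lost without clone 1 (0.0792) or clone 3 (0.0713) at passage 7, proximal-distal genes without GFP at passage 7 (0.07), and let-7 targets without GFP at passage 7 (0.0535) or clone 3 at passage 5 (0.0727) or 7 (0.0577). The goblet, PLAG family and Notch lists passed without any 1 library.

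Clone 3, the line with the higher Plagl2 value, differed from GFP in 32 higher and 25 lower genes. Cyp2w1, a cytochrome P450, rose from an RPKM of 1.29 ± 0.0151 to 44.0 ± 3.82 (SD, n = 2 each), a log2 change of 4.64 (SE 0.13, adjusted p = 0.0011). Nes, which encodes the intermediate filament protein nestin, rose from 0.225 ± 0.0659 to 14.1 ± 1.26 (log2 change 4.33, SE 0.16, adjusted p = 0.002). Gpc3, a cell surface heparan sulfate proteoglycan of embryonic tissues, rose from 0.119 ± 0.0536 to 9.16 ± 0.333 (log2 change 3.97, SE 0.17, adjusted p = 0.00348). H19, an imprinted long non-coding RNA, rose from 0.0127 ± 0.0180 to 9.02 ± 3.53 (log2 change 4.16, SE 0.29, adjusted p = 0.0144), that is from 1 and 0 reads to 258 and 412. Sdr16c5, a retinol dehydrogenase, rose to 14.6 ± 1.5 from 0.327 ± 0.192 (log2 change 4.21, adjusted p = 0.00683). Ctrb1, a digestive protease precursor, rose to 319 ± 141 from 19.4 ± 1.66 (log2 change 3.93, adjusted p = 0.0178).

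The largest fall in clone 3 was that of Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260771 to 1286629), from 11.6 ± 0.471 to 0.0377 ± 0.0369 (log2 change -4.50, SE 0.14, adjusted p = 0.00113). Mmp14 followed at a log2 change of -4.05 (SE 0.20, adjusted p = 0.00606). Without either GFP library it no longer met the expression filter and was not tested. Cd177, a glycoprotein known from neutrophils, fell from 22.6 ± 2.44 to 2.28 ± 1.31 (log2 change -3.14, adjusted p = 0.0482). Rhbdl2, an intramembrane protease, fell from 3.65 ± 0.0247 to 0.180 ± 0.172 (log2 change -2.63, adjusted p = 0.0251). The elastase gene Cela1 fell from 8.86 ± 1.83 to 1.07 ± 0.439 (log2 change -2.59, adjusted p = 0.0386). S100a6, a calcium-binding protein, fell from 28.2 ± 4.51 to 5.00 ± 0.230 (log2 change -2.38, adjusted p = 0.0116). At an unadjusted p under 0.05 there were 874 genes higher and 600 lower. The counts were 199 higher and 143 lower with the replicate block and 86 higher and 53 lower with voom. Leaving out a library gave 5 genes without GFP at passage 5, 11 without GFP at passage 7, 10 without clone 1 at either passage, 2 without clone 3 at passage 5 and 4 without clone 3 at passage 7. Cyp2w1 and Ddx3y passed in all of these fits, with adjusted p of at most 0.0229 and 0.0257. Nes was lost without clone 3 at passage 5 (0.0568), Gpc3 (0.0628 and 0.0646), Mmp14 (0.0628 and 0.0646) and Sdr16c5 (0.104 and 0.0646) without clone 3 at passage 5 or 7. S100a6 was lost without GFP at passage 5 (0.0716) or clone 3 at passage 5 (0.13) or 7 (0.0909). Ctrb1 passed only without clone 3 at passage 7 and reached 0.134. H19, Cd177, Rhbdl2 and Cela1 passed in none of the 6 fits and reached 0.103, 0.244, 0.21 and 0.246. With a pseudocount of 0.1 Cd177 (0.0624), Rhbdl2 (0.0624) and Cela1 (0.0531) were lost, as they were with no filter (0.0813, 0.0523 and 0.0739).

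**Figure D1:**
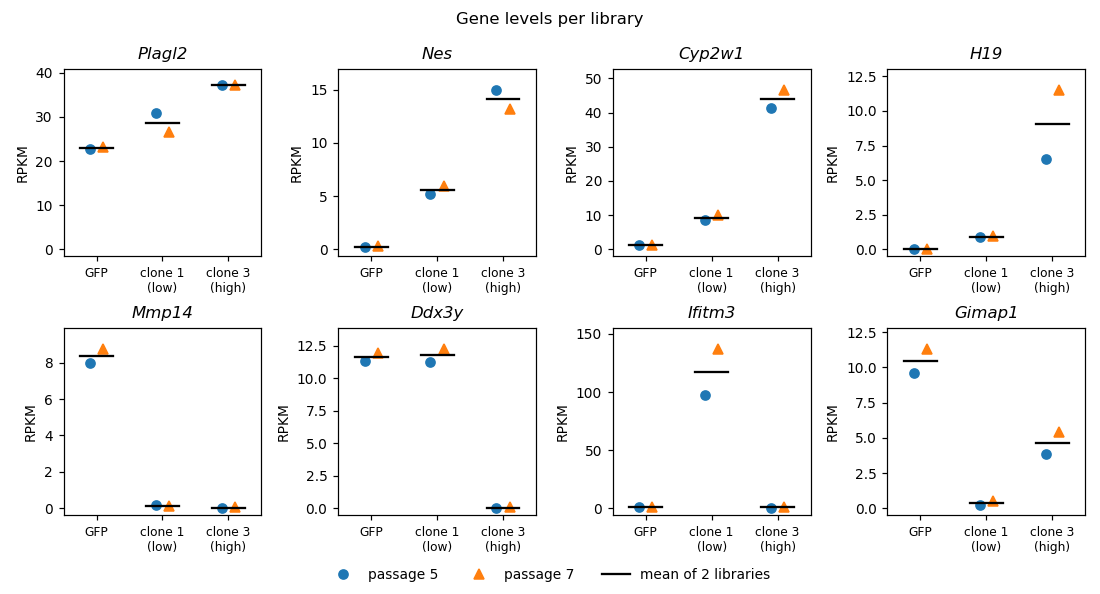
RPKM of 8 genes in GFP, PLAGL2 clone 1 and PLAGL2 clone 3, with circles for passage 5, triangles for passage 7 and bars for the mean of the 2 libraries. Mmp14 lies near 0 in both PLAGL2 lines, Ddx3y near 0 in clone 3 but not in clone 1 or GFP, Ifitm3 at a mean of 117 in clone 1, and Cyp2w1 at means of 1.29, 9.25 and 44.0.

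Goblet cell genes were lower in clone 3 throughout the list. Muc2, the main gel-forming mucin of the intestine, fell from 96.3 ± 21.5 in GFP to 25.7 ± 0.149 in clone 3 (SD, n = 2 each), a log2 change of -1.87 (SE 0.16, adjusted p = 0.0251), and stood at 49.7 ± 4.01 in clone 1. Fcgbp, a mucus protein that binds immunoglobulin G, fell from 238 ± 34.8 to 69.7 ± 1.049 (log2 change -1.76, SE 0.12, adjusted p = 0.0144), with 145 ± 2.95 in clone 1. Agr2, which folds mucins in the endoplasmic reticulum, fell from 108 ± 3.08 to 47.9 ± 2.35 (log2 change -1.17, SE 0.09, adjusted p = 0.0172), with 80.9 ± 5.12 in clone 1. The 20 tested members were all lower, with a median log2 change of -1.03 (camera adjusted p = 2.19e-27, adjusted p = 0.193 with an estimated correlation, fry adjusted p = 0.0173). Of these, 3 passed over all genes, 11 with the replicate block, and 18 when adjusted over the list alone. The list passed without any 1 library, with adjusted p of at most 1.98e-17. Muc2 passed only without GFP at passage 7 (0.0393) and so did Fcgbp (0.0393), with adjusted p up to 0.161 and 0.13 without another library, and Agr2 passed in none of the 6 fits, with adjusted p of 0.0634 to 0.173.

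**Figure D2:**
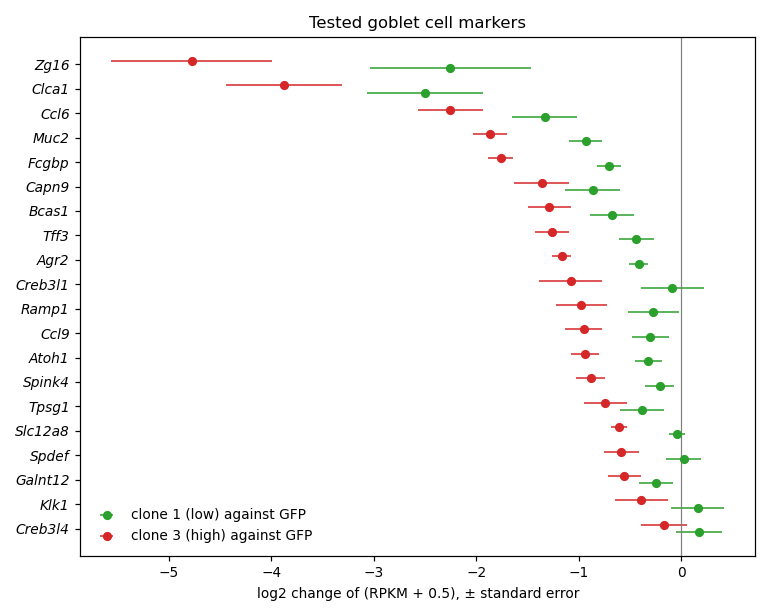
Log2 change against GFP of the 20 tested goblet cell genes in clone 1 and in clone 3, each with its standard error. In clone 3 all 20 lie below 0, with a median of -1.03, and in clone 1 17 of 20 do, with a median of -0.35.

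Reported PLAG family targets were higher in clone 3, with a median log2 change of 0.79 over 14 tested genes, of which 12 were higher (adjusted p = 1.7e-09, adjusted p = 0.143 with an estimated correlation, fry adjusted p = 0.0173). Of these, 2 passed over all genes, H19 and Cdkn1c, 3 with the replicate block and 10 when adjusted over the list alone. Cdkn1c rose from 2.94 ± 0.146 to 8.03 ± 0.956 (SD, n = 2 each; log2 change 1.31, SE 0.14, adjusted p = 0.0482) and passed in none of the fits without 1 library (0.128 to 0.286), nor with a pseudocount of 0.1 (0.0524), no filter (0.0739) or quantile normalization (0.0564). Antimicrobial and immune epithelial genes were lower, with a median of -0.46 (adjusted p = 0.00205, adjusted p = 0.24 with an estimated correlation, fry adjusted p = 0.0283). Of these 0 passed over all genes, 3 were lower with the replicate block, and 3 were lower (5 with the block) and 1 higher when adjusted over the list alone. Duox2, an oxidase that makes hydrogen peroxide at the mucosa, was at 5.53 ± 0.872 in GFP and 1.31 ± 0.283 in clone 3 (adjusted p = 0.0603, 0.0375 with the replicate block, range over the alternatives 0.000407 to 0.285). Reg1 was at 17.3 ± 0.462 and 104 ± 71.9 (adjusted p = 0.174, range 0.0303 to 0.556). Without clone 3 at passage 7 the antimicrobial list was lost (adjusted p = 0.0716).

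The other lists of secretory cells differed in direction in clone 3. Paneth cell genes, which encode lysozyme and defensins of the crypt base, had a median log2 change of -0.33 (adjusted p = 0.00518, adjusted p = 0.662 with an estimated correlation). Enteroendocrine genes, which mark hormone-secreting cells, had one of 0.44, with 19 of 25 higher (adjusted p = 0.0119, adjusted p = 0.849 with an estimated correlation). Lyz1, the Paneth cell lysozyme, was at 722 ± 24.9 in GFP and 241 ± 60.7 in clone 3 (log2 change -1.60, SE 0.20, adjusted p = 0.0624, 0.0187 with the replicate block, range over the alternatives 7.92e-05 to 0.313). Against the direction of its list, Fgfrl1, a decoy receptor for fibroblast growth factors, was at 9.29 ± 1.31 and 25.4 ± 6.70 (adjusted p = 0.0998, 0.0138 with the replicate block, range 0.000131 to 0.415). Among hormones, Sst (somatostatin) was at 4.85 ± 1.88 and 1.59 ± 0.410 (adjusted p = 0.347, 0.0375 with the replicate block, range 0.0152 to 0.837). Chga, a protein of secretory granules, was at 37.8 ± 8.11 and 49.8 ± 18.9 (adjusted p = 0.883, range over the alternatives 0.0456 to 1). Of Paneth genes 0 passed over all genes, with 4 lower and 2 higher when adjusted over the list alone, and of enteroendocrine genes 0 passed by either count. With the replicate block 4 Paneth genes were lower and 1 higher over all genes, and 7 lower and 3 higher over the list alone. Of enteroendocrine genes 1 was then higher and 1 lower over all genes, and 9 higher and 2 lower over the list alone. The Paneth list was lost without clone 3 at passage 5 (adjusted p = 0.0772) and the enteroendocrine list without GFP at passage 5 (0.317) or clone 3 at passage 7 (0.961).

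Genes of signalling pathways lay slightly higher in clone 3. The Notch pathway list had a median log2 change of 0.26 (adjusted p = 8.29e-04, adjusted p = 0.616 with an estimated correlation), Wnt ligands and receptors 0.36 (adjusted p = 0.00254, adjusted p = 0.616 with an estimated correlation) and Wnt targets 0.22 (adjusted p = 0.0217, adjusted p = 0.849 with an estimated correlation). For p53 targets the median was 0.17 (adjusted p = 0.00518, adjusted p = 0.616 with an estimated correlation), for let-7 targets 0.06 (adjusted p = 0.012, adjusted p = 0.523 with an estimated correlation) and for proximal-distal genes 0.14 (adjusted p = 0.012, adjusted p = 0.344 with an estimated correlation). Notch1, a Notch receptor, was at 9.50 ± 0.857 in GFP and 16.2 ± 3.64 in clone 3 (adjusted p = 0.239). Wnt5a, a ligand of non-canonical Wnt signalling, was at 0.0517 ± 0.0187 and 1.37 ± 0.0454 (adjusted p = 0.0651, 0.0435 with the replicate block, range over the alternatives 0.000577 to 0.357). Of the genes in these 6 lists 0 passed over all genes, and adjusted over the list alone 3 Wnt ligand and receptor genes and 4 let-7 targets were higher, and 2 p53 targets were higher and 1 lower. Over all genes 2 Wnt ligand and receptor genes, 1 Wnt target and Plagl2 from the let-7 list were higher with the replicate block. Over the list alone the block gave 8 higher and 2 lower Wnt ligand and receptor genes, 6 higher and 2 lower p53 targets, and 5 Wnt targets, 3 Notch genes and 1 proximal-distal gene higher. The 4 let-7 targets include Plagl2, the introduced gene, and without it 3 were higher and the list had an adjusted p = 0.0499 (0.616 with an estimated correlation). Without clone 3 at passage 7 the adjusted p was 0.0521 for Wnt ligands and receptors and 0.963 for Wnt targets, which turned downward and were also lost without GFP at passage 5 (0.387). The p53 list was lost without GFP at passage 7 (0.066), the let-7 list without clone 3 at passage 5 (0.106), and the proximal-distal list without GFP at passage 7 (0.057) or clone 3 at passage 5 (0.0534).

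The remaining 11 lists did not pass in clone 3. Their median log2 changes and adjusted p were 0.18 and 0.151 for stem cell genes, -0.19 and 0.0901 for tuft cell genes, -0.06 and 0.215 for replication-dependent histones, -0.08 and 0.426 for cholesterol synthesis and -0.23 and 0.426 for non-epithelial genes. They were 0.09 and 0.432 for gastric and colonic genes, -0.08 and 0.432 for mitochondrially encoded genes, and -0.06 and 0.464 for interferon response. They were -0.10 and 0.595 for enterocyte genes, -0.38 and 0.595 for fetal-like genes and 0.01 and 0.759 for the cell cycle, whose test pointed down and whose mean was 0. With the replicate block the tuft list (0.0217) and the histone list (0.0273) passed, but not with an estimated correlation (0.43 and 0.453). Over all genes the block gave 3 higher stem cell genes, 4 higher and 2 lower enterocyte genes and 1 fetal-like gene each way, against 0 without it. Over the list alone it gave 7 higher and 1 lower stem cell genes, against 2 and 0 without it. For enterocyte genes these counts were 9 higher and 12 lower against 0 and 0, and for fetal-like genes 4 and 3 against 1 and 1. For the cell cycle they were 0 and 1 against 0 and 0. Lgr5 was at 57.4 ± 25.7 in clone 3 (SD, n = 2; adjusted p = 0.706, 0.0616 with the replicate block, range over the alternatives 0.00207 to 0.997), and Ascl2 at 26.5 ± 15.9 (0.602, 0.0615 with the block, range 0.00413 to 0.997). Both passed only with voom and the block together. Olfm4, a secreted glycoprotein of stem cells, was at 1126 ± 397 against 932 ± 177 in GFP (0.95). Mki67, a protein of dividing cells, was at 106 ± 17.5 against 99.9 ± 16.5 (0.975) and Dclk1, a kinase of tuft cells, at 1.72 ± 0.386 against 2.10 ± 0.788 (0.954). Tert, the reverse transcriptase of telomerase, was at 4.72 ± 0.00894 and 9.72 ± 0.00230 (adjusted p = 0.0624, 0.0309 with the replicate block, range over the alternatives 0.000652 to 0.354). The brush border enzymes Alpi and Lct were at 53.7 ± 26.9 and 5.91 ± 3.94 in GFP and at 84.1 ± 43.9 and 46.2 ± 30.6 in clone 3, with adjusted p of 0.892 and 0.264. Both passed with the replicate block (0.0325 and 0.00177, with ranges over the alternatives of 0.000593 to 0.99 and 2.66e-06 to 0.686), as did Mep1a, a brush border protease, at 12.7 ± 3.43 and 21.5 ± 5.92 (adjusted p = 0.462, 0.0369 with the block, range 0.000947 to 0.948). Of fetal-like genes, Msln, the surface protein mesothelin, was at 0.531 ± 0.216 and 2.67 ± 0.402 (adjusted p = 0.0854, 0.0296 with the block, range 0.00133 to 0.338). The keratin gene Krt7 was at 25.7 ± 1.07 and 13.7 ± 2.87 (adjusted p = 0.12, 0.0375 with the block, range 0.000578 to 0.447).

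**Figure D3:**
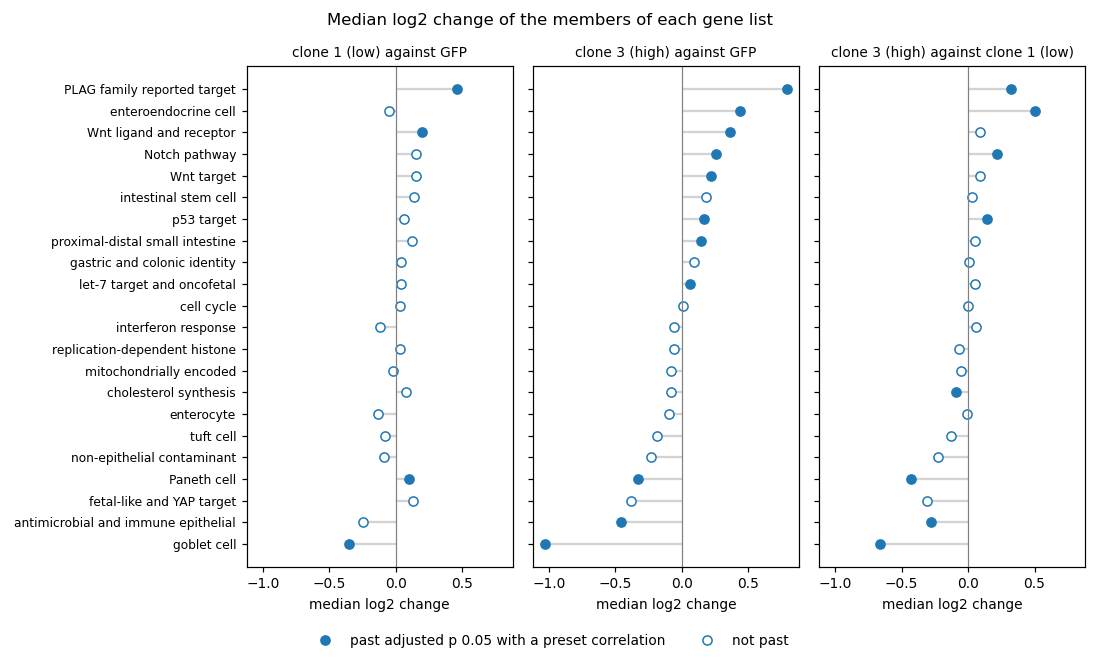
Median log2 change of the 22 gene lists in clone 1 against GFP, clone 3 against GFP and clone 3 against clone 1, with filled symbols for lists past adjusted p 0.05 by camera with the preset correlation. The goblet cell list has the lowest value in each contrast, at -0.35, -1.03 and -0.66, and none of the lists passes with an estimated correlation.

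Clone 1, the line with the lower Plagl2 value, differed from GFP in 3 higher and 2 lower genes. Ifitm3 (chromosome 7, 141009586 to 141010770), a membrane protein that restricts virus entry, rose from 1.14 ± 0.356 to 117 ± 28.1 (SD, n = 2 each), a log2 change of 6.16 (SE 0.27, adjusted p = 0.0119), while clone 3 had 0.848 ± 0.323. Nes rose from 0.225 ± 0.0659 to 5.57 ± 0.534 (log2 change 3.07, SE 0.16, adjusted p = 0.0119) and Cyp2w1 from 1.29 ± 0.0151 to 9.25 ± 1.04 (log2 change 2.45, SE 0.13, adjusted p = 0.0119). Mmp14 fell to 0.128 ± 0.0395 (log2 change -3.82, SE 0.20, adjusted p = 0.0119), and without either GFP library it was not tested. Gimap1, a GTPase known from lymphocytes, fell from 10.5 ± 1.20 to 0.366 ± 0.168 (log2 change -3.67, SE 0.23, adjusted p = 0.0239) and was at 4.65 ± 1.09 in clone 3. At an unadjusted p under 0.05 there were 355 genes higher and 289 lower, where chance gives 816 in all. The counts were 5 higher and 7 lower with the replicate block and 4 higher and 6 lower with voom. Lct passed with the block (29.9 ± 17.4 against 5.91 ± 3.94 in GFP, adjusted p = 0.00558, range over the alternatives 6.07e-06 to 1). Of these genes 0 passed once any of the 6 libraries was left out, with adjusted p from 0.0522 for Ifitm3 without clone 3 at passage 5 up to 0.267 for Gimap1 without GFP at passage 5. With a pseudocount of 0.1 Mmp14 (0.092) and Gimap1 (0.0586) were lost.

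As groups in clone 1, goblet cell genes were lower, with a median log2 change of -0.35 and 17 of 20 lower (adjusted p = 1.31e-12, adjusted p = 0.535 with an estimated correlation). Of these 0 passed over all genes, 2 with the replicate block and 5 when adjusted over the list alone (9 with the block). PLAG family targets were higher, with a median of 0.46 and 13 of 14 higher (adjusted p = 2.37e-07, adjusted p = 0.208 with an estimated correlation), with 0 past over all genes and 2 when adjusted over the list alone (6 with the block). Wnt ligands and receptors had a median of 0.20 (adjusted p = 0.00747, adjusted p = 0.875 with an estimated correlation) and Paneth genes one of 0.10 (adjusted p = 0.0492, adjusted p = 0.958 with an estimated correlation), each with 0 members past over all genes, and with 0 and 1 when adjusted over the list alone (0 and 2 with the block). The goblet and PLAG family lists passed without any 1 library. Wnt ligands and receptors were lost without GFP at passage 5 (0.146) or clone 1 at passage 7 (0.0956), and Paneth genes without GFP at passage 5 (0.0794), clone 1 at passage 5 (0.0706) or clone 3 at passage 5 (0.0698) or 7 (0.0652), with no filter (0.0802) and with median ratio scaling (0.0537). With the replicate block 10 lists passed, the additional ones being Wnt target (6.47e-04), stem cell (6.47e-04), enteroendocrine (0.00485, lower), Notch pathway (0.00704), cholesterol synthesis (0.0117) and antimicrobial (0.0241, lower). With the block and an estimated correlation 0 lists passed, with adjusted p of 0.55 to 0.662 for these 6. Over all genes the block gave 1 lower enteroendocrine gene, against 0 without it. Over the list alone it gave 2 lower enteroendocrine genes, against 0 without it. It also gave 2 lower and 1 higher antimicrobial genes there, against 0 and 1 without it.

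Compared directly, clone 3 and clone 1 differed in 1 higher and 3 lower genes. Cyp2w1 was higher in clone 3, at 44.0 ± 3.82 against 9.25 ± 1.04 (SD, n = 2 each; log2 change 2.19, SE 0.13, adjusted p = 0.0234). Ifitm3 was lower, at 0.848 ± 0.323 against 117 ± 28.1 (log2 change -6.45, SE 0.27, adjusted p = 0.00627), and so was Ddx3y, at 0.0377 ± 0.0369 against 11.7 ± 0.699 (log2 change -4.51, SE 0.14, adjusted p = 0.00221). The unnamed gene model Gm21887 (annotated at chromosome X, 170009659 to 170019281), chosen after its values were seen, was at 0.0874 ± 0.124 against 12.6 ± 2.68 (log2 change -4.48, SE 0.27, adjusted p = 0.0236). At an unadjusted p under 0.05 there were 453 genes higher and 384 lower. The counts were 23 higher and 24 lower with the replicate block. There Fcgbp (0.0471), Agr2 (0.0475), Defa26, a Paneth cell defensin (0.0475), and Ghrl, which encodes ghrelin (0.0238), also passed, with ranges over the alternatives of 3.05e-04 to 0.564, 0.00123 to 0.67, 0.0111 to 0.968 and 0.00715 to 1. Voom gave 16 higher and 7 lower, median ratio scaling 3 higher and 4 lower, and quantile normalization 7 higher and 8 lower. The count was 0 without clone 1 at passage 5 or at passage 7, 1 without clone 3 at passage 5 or 7 and 2 without GFP at passage 5 or 7. Without clone 1 at passage 5 and at passage 7, Ddx3y and Ifitm3 both had adjusted p of 0.0611 and 0.0928. Ifitm3 was also lost without clone 3 at passage 5 (0.0959) or 7 (0.0718), and Cyp2w1 was lost without each library (0.0701 to 0.285). The level of PLAGL2 and the clone of origin cannot be separated in this comparison.

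As groups, goblet cell genes were lower in clone 3 than in clone 1 in all 20 members, with a median log2 difference of -0.66 (adjusted p = 6.73e-25, adjusted p = 0.219 with an estimated correlation), of which 0 passed over all genes, 5 with the replicate block and 14 when adjusted over the list alone. Paneth genes were lower by a median of -0.43 (adjusted p = 4.81e-08, adjusted p = 0.479 with an estimated correlation) and antimicrobial genes by -0.28 (adjusted p = 0.0015, adjusted p = 0.236 with an estimated correlation). The median was -0.09 for cholesterol synthesis (adjusted p = 0.0311, adjusted p = 0.926 with an estimated correlation). Enteroendocrine genes were higher in 23 of 25 members, with a median of 0.50 (adjusted p = 4.26e-06, adjusted p = 0.828 with an estimated correlation). For PLAG family targets the median was 0.32 (adjusted p = 2.59e-05, adjusted p = 0.219 with an estimated correlation), for Notch genes 0.22 (adjusted p = 0.00901, adjusted p = 0.828 with an estimated correlation) and for p53 targets 0.14 (adjusted p = 0.00203, adjusted p = 0.725 with an estimated correlation). Beyond the goblet list 0 members of these lists passed over all genes, and adjusted over the list alone 7 Paneth genes and 1 p53 target were lower, 3 PLAG family targets were higher and 0 of the others passed. Over all genes 2 Paneth genes were lower and 2 enteroendocrine genes higher with the replicate block. Over the list alone the block gave 12 lower and 1 higher Paneth genes, 14 higher and 1 lower enteroendocrine genes, 2 lower antimicrobial genes and 2 higher p53 targets. The block added the histone list (0.00108, lower), but not with an estimated correlation (0.542). Without clone 1 at passage 5 the antimicrobial (0.0835) and Notch (0.129) lists were lost and the cholesterol list turned upward without passing (0.249), and without clone 1 at passage 7 the p53 list (0.566). Without clone 3 at passage 7 were lost the enteroendocrine (0.199) and Notch (0.416) lists, and the cholesterol list then turned upward and passed (0.0172). The cholesterol list was also lost with median ratio scaling (0.0879) and quantile normalization (0.105).

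Both clones shared 3 called genes, Nes and Cyp2w1, which rose in each, and Mmp14, which fell in each. Independent lists of these sizes would share 0.00588 higher and 0.00306 lower genes, a figure that leaves out the GFP controls common to both clones. The clones shared 8 genes with the replicate block, among them Gimap1, Lct and the goblet genes Clca1 and Zg16. Across all 16314 genes, which are not independent replicates, the log2 changes of the clones correlated at r = 0.60, against 0.50 on average in 100 simulations of unchanged lines that share these controls. Their covariance was 0.081 against a simulated 0.037, a difference of 0.044. The 2 GFP libraries cannot be split into separate controls for each clone, and without either of them Mmp14 did not meet the expression filter. Without any 1 library, and in fits on the libraries of 2 lines alone, the overlap was 0.

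Between passages 5 and 7, sampled in each of the 3 lines, genes of absorptive cells fell. Slc2a5, the fructose transporter, fell from 58.6 ± 12.7 at passage 5 to 15.5 ± 2.63 at passage 7 (SD, n = 3 lines each), a log2 change of -1.88 (SE 0.05, adjusted p = 0.00508). Slc2a7, another hexose transporter, fell from 9.88 ± 0.336 to 2.48 ± 0.537 (log2 change -1.82, SE 0.11, adjusted p = 0.0109). Apoa4, an apolipoprotein of chylomicrons, fell from 1009 ± 346 to 309 ± 141 (log2 change -1.78, SE 0.18, adjusted p = 0.0186), and Alpi, the brush border alkaline phosphatase, from 103 ± 26.0 to 45.7 ± 9.79 (log2 change -1.15, SE 0.05, adjusted p = 0.00989). Gcg, which encodes glucagon-like peptides, rose from 13.4 ± 4.49 to 35.2 ± 11 (log2 change 1.36, SE 0.04, adjusted p = 0.00508). The small nucleolar RNA Snord13 rose from 1.53 ± 0.684 to 3.94 ± 0.865 (log2 change 1.16, adjusted p = 0.0201) and the mitochondrial transfer RNA mt-Tr from 19.5 ± 3.04 to 39.6 ± 3.02 (log2 change 1.01, adjusted p = 0.023). For RNAs much shorter than 1 kb, such as these, the floor in RPKM lies above that given for 1 kb. The Snord13 values may thus rest on few reads. Moving the same way in all 3 lines was a condition for naming these genes, apart from Alpi, which was always given and also fell in all 3.

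Stem cell genes rose over the same passages. Lgr5 rose from 34.6 ± 7.69 to 57.3 ± 17.3 (log2 change 0.70, SE 0.09, adjusted p = 0.0251), Ascl2 from 12.2 ± 4.11 to 24.3 ± 12.2 (log2 change 0.91, SE 0.15, adjusted p = 0.0337) and Olfm4 from 853 ± 50.1 to 1315 ± 227 (log2 change 0.61, SE 0.09, adjusted p = 0.0291), with n = 3 lines each. Mki67 rose from 91.7 ± 3.05 to 115 ± 3.42 (log2 change 0.33, SE 0.03, adjusted p = 0.018) and Chga from 32.5 ± 3.77 to 48.7 ± 12.6 (log2 change 0.56, SE 0.08, adjusted p = 0.0309). Plagl2 was at 30.3 ± 7.22 and 28.9 ± 7.34 (adjusted p = 0.479). In all, 1111 genes were higher and 864 lower at passage 7, against 481 higher and 1127 lower with median ratio scaling and 771 higher and 888 lower with quantile normalization. Voom gave 2724 higher and 1362 lower, and the count at an unadjusted p under 0.05 was 5439. With the line as a term, leaving out 1 library takes its whole line out of the passage change. The fits without either library of a line are therefore not separate checks. The count of called genes was 0 without either GFP library or either clone 1 library, 762 without clone 3 at passage 5 and 730 without clone 3 at passage 7. Without a GFP or clone 1 library the named genes were all lost, with adjusted p of 0.0636 to 0.165. Without clone 3 at passage 5 or 7 Ascl2 (0.0521 and 0.0534), Olfm4 (0.0689 and 0.0701) and Snord13 (0.0551 and 0.0583) were lost. With no filter Lgr5 (0.0562), Ascl2 (0.0726), Olfm4 (0.0758), Chga (0.0656) and mt-Tr (0.0527) were lost, and without the line as a term Lgr5 (0.146), Ascl2 (0.211), Chga (0.116), Gcg (0.0616) and Apoa4 (0.0625). Quantile normalization lost Olfm4 (0.0623), and voom lost Snord13 (0.0796).

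**Figure D4:**
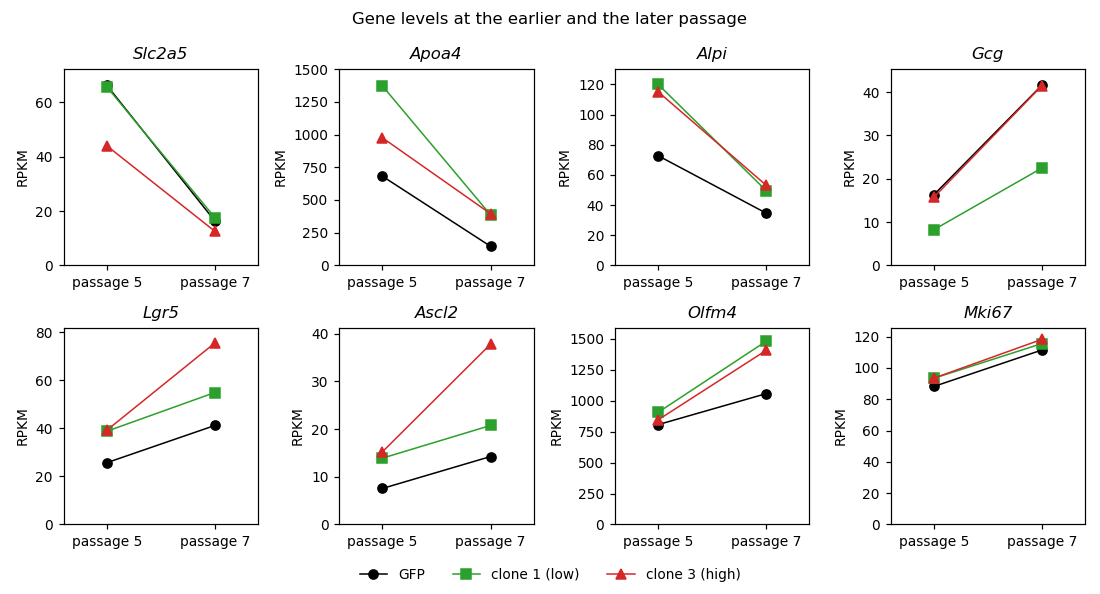
RPKM of 8 genes at passage 5 and passage 7, with 1 line per enteroid line (GFP, clone 1 and clone 3). Slc2a5, Apoa4 and Alpi are lower at passage 7 in all 3 lines, and Gcg, Lgr5, Ascl2, Olfm4 and Mki67 are higher in all 3.

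At the level of single transcripts, PLAGL2 and GFP differed in 0 higher and 2 lower isoforms by limma-trend. The isoform Me3-003 of a mitochondrial malic enzyme fell from 28.1 ± 1.29 in GFP (SD, n = 2) to 6.54 ± 0.101 with PLAGL2 (SD, n = 4), a log2 change of -2.02 (SE 0.09, adjusted p = 0.0132). Mmp14-001 fell from 6.07 ± 0.306 to 0.0627 ± 0.0488 (log2 change -3.55, SE 0.22, adjusted p = 0.047), in the same direction as its gene. For Plagl2 itself, isoform Plagl2-001 was at 12.4 ± 0.0434 in GFP, 12.3 ± 0.620 in clone 1 and 13.7 ± 0.163 in clone 3. Plagl2-002 was at 2.10 ± 0.132, 2.14 ± 0.173 and 4.09 ± 0.244 (adjusted p = 0.92 and 0.427 for clone 3 against GFP). The higher gene value of clone 1 was thus not seen in Plagl2-001 and hardly in Plagl2-002. At an unadjusted p under 0.05 there were 1462 transcripts higher and 1021 lower of 44747, where chance gives 2237. With the replicate block 1 isoform passed. The count was 4 without GFP at passage 5, 6 without GFP at passage 7, and 0 without either clone 1 library or either clone 3 library.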

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

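The tests of the regions, of the Y chromosome, of Ddx3x and of the goblet cell list below were chosen only after those results were seen, the test of Ddx3x before its own values.

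The change against GFP differed between the clones for 4 genes, which is the same test as the direct comparison of clone 3 with clone 1. The log2 difference, clone 3 minus clone 1, was -4.51 for Ddx3y, -6.45 for Ifitm3, 2.19 for Cyp2w1 and -4.48 for Gm21887, a gene model annotated on chromosome X and chosen after its values were seen. Among gene lists the median difference was -0.66 for goblet cell genes, -0.43 for Paneth genes, -0.28 for antimicrobial genes and -0.09 for cholesterol synthesis. It was 0.50 for enteroendocrine genes, 0.32 for PLAG family targets, 0.22 for Notch genes and 0.14 for p53 targets. With an estimated correlation 0 of these lists passed. The level of PLAGL2 and the clone of origin are the same variable here, so no biological explanation of these differences was tested.

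Mmp14, Ddx3y, Ifitm3 and Gimap1 were near 0 in some lines and not in others. Loss of the Y chromosome in clone 3 does not account for Ddx3y, since the smallest ratio to GFP among Eif2s3y, Uty and Kdm5d was 0.996, and Ddx3x differed by -2.03 RPKM (SE 2.37) where Ddx3y had lost 11.6, so its reads were not moved to that paralog. In clone 3 against GFP, the median log2 change of tested genes within 500 kb was 0.01 around Mmp14 (27 genes) and -0.02 around Ddx3y (7 genes). In clone 1 against GFP it was -0.01 around Ifitm3 (43 genes) and -0.03 around Gimap1 (14 genes). These medians speak against a change of a whole region in the clone named. The region around Mmp14 was not tested in clone 1. Smaller local changes stay possible, since Gimap5 had a log2 change of -3.14 (adjusted p = 0.129). Within the span of Ddx3y, the pseudogene Gm4017 had one of -2.51 (adjusted p = 0.0313). Gm18665, which starts within that span, had one of -1.99 (adjusted p = 0.174). The other tested genes around Ddx3y lay between -0.10 and 0.21. Gimap5, Gm4017 and Gm18665 were chosen after their values were seen. No genome sequence of the lines was at hand, so insertion of the transposon, a deletion within a gene and a response to PLAGL2 could not be told apart. With a single GFP line, a gain of Mmp14 in that line stays possible too.

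The goblet cell list was lower in clone 3, with a median log2 change of -1.03, and of its 20 tested members 18 were lower when adjusted over the list alone (13 to 19 with 1 library left out, fewest without clone 3 at passage 5), so a few abundant members do not account for it. Its median lay at -1.04 from that of the other tested genes (-1.15 to -0.91 with 1 library left out), a gap that a factor on a whole library leaves as it is, so the scaling of the libraries does not account for it. Whether secretory cells of every type were lost stays open, since the medians of the Paneth and tuft lists were -0.33 and -0.19 and that of the enteroendocrine list was 0.44, with 0 genes called (1 higher and 1 lower with the replicate block) and an adjusted p = 0.849 with an estimated correlation, and 0.961 without clone 3 at passage 7. With an estimated correlation, which was 0.289, the goblet list had a camera adjusted p = 0.193. PLAG family targets, with an estimated correlation of -0.003, were lost as well (camera adjusted p = 0.143). The loss therefore does not show that goblet markers moved together. A shift of 1 shared cell type, which moves all its markers together, and a change of expression within cells are both possible. PLAGL2 level cannot be set against clone of origin as a biological explanation.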

How the results depend on the processing

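Of the alternatives in this part, voom on recovered reads and the let-7 list without Plagl2 were chosen after seeing the data and the others before. Among values of named genes 3741 kept their side of the threshold, 109 newly passed and 195 no longer passed, and the 49 that changed sign passed neither before nor after. Among values of gene lists 1100 kept their side, 93 newly passed and 103 no longer passed. A further 18 list values changed sign and passed before or after, all with a library left out. Of the 1100, 69 changed sign and passed neither before nor after, 21 of them with no library left out.

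Counts of genes moved as follows, and except where the construction of a setting is named the cause was not tested. For PLAGL2 against GFP, 1 gene became 0 with a pseudocount of 0.1, 17 with no filter, 2 with the replicate block, 23 in the 3-group fit, 8 with voom and 33 with voom and the block. For clone 1 against GFP, 5 became 3 with a pseudocount of 0.1, 22 with no filter, 12 with the block, 0 in the libraries of both groups alone, 10 with voom and 288 with voom and the block. For clone 3 against GFP, 57 became 342 with the block, 8 in the groups alone, 139 with voom and 1514 with voom and the block. For clone 3 against clone 1, 4 became 23 with no filter, 8 at an RPKM of at least 1, 7 with median ratio scaling, 15 with quantile normalization, 47 with the block, 2 in the groups alone, 23 with voom and 441 with voom and the block. For passage, 1975 became 629 with no filter and 4086 with voom. The 2 transcripts became 5 with a pseudocount of 0.1, 16 with no filter, and 1 at an RPKM of at least 1, with robust moderation, with the block and in the 3-group fit. The overlap of 3 genes became 11 with no filter, 8 with the block, 0 in the groups alone, 5 with voom and 242 with voom and the block. Fits on the groups alone hold fewer libraries. The block changed no other call of a named gene or list than those given with the results.

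Lists past the threshold numbered 0 in every contrast with an estimated correlation. With fry they numbered 0 for PLAGL2 against GFP, clone 1 against GFP and clone 3 against clone 1, 3 for clone 3 against GFP and 8 for passage. No filter gave 5 lists in place of 8 for PLAGL2 against GFP, where the antimicrobial (0.153), proximal-distal (0.0964) and let-7 (0.117) lists were lost, and the let-7 list was also lost with median ratio scaling (0.0631) and without Plagl2 (0.122). The block gave 10 lists in place of 4 for clone 1. In clone 3 no filter lost the antimicrobial (0.165) and proximal-distal (0.0611) lists, and against clone 1 the antimicrobial list (0.282).

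Leaving out 1 library unbalances the passages and leaves a line with 1 library, which is assumed to vary like the others. It also takes 1 residual degree of freedom from the fit, so a lost call need not rest on the values of that library. In the passage contrast, leaving out 1 library takes its whole line out of the change. In clone 3 against GFP, H19 and Muc2 were lost without a clone 1 library, which has no part in that contrast. Their log2 changes stayed at 4.164 and -1.867. Counts of genes then ranged from 0 to 3 for PLAGL2 against GFP, were 0 for clone 1, and ranged from 2 to 11 for clone 3, 0 to 2 for clone 3 against clone 1, 0 to 762 for passage and 0 to 6 for transcripts. The overlap was 0. Lists numbered 7 to 11, 5 to 12, 11 to 14 and 8 to 13 in the 4 contrasts of lines.

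Adjusted p of lists that changed sign and passed before or after ranged, for the cell cycle, from 0.00504 to 0.517 for PLAGL2 against GFP and from 0.00116 to 0.522 for clone 1. For enterocyte genes it ranged from 2.52e-07 to 0.493 for PLAGL2, 1.06e-06 to 0.679 for clone 1, 3.29e-05 to 0.572 for clone 3 and 1.77e-04 to 0.799 for clone 3 against clone 1. For cholesterol synthesis it ranged from 7.05e-06 to 0.374 for clone 1, 9.49e-06 to 0.445 for clone 3 and 7.81e-10 to 0.249 for clone 3 against clone 1. Histones in clone 1 ranged from 0.00484 to 0.838, stem cell genes in clone 3 against clone 1 from 0.00148 to 0.738, and Wnt targets from 1.6e-05 to 0.963 in clone 3 and 4.14e-04 to 0.481 against clone 1.

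Count tests planned for the case that counts were given were not run, because the values are RPKM. Depth limits low genes, since a listed 0 allows up to 3 reads, an RPKM of 0.173 to 0.218 for a gene of 1 kb.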

Other observations

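The tests of lists between passages, of depth, of GC content, of imprinted genes and of the order of the lines were chosen only after the results were seen.

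Enterocyte genes, which serve digestion and absorption, were lower at passage 7 than at passage 5, with a median log2 change of -1.01 and 30 of 33 members called lower (adjusted p = 9.7e-28, adjusted p = 0.309 with an estimated correlation). Slc2a2, a glucose transporter, fell from an RPKM of 47.5 ± 6.79 to 16.9 ± 2.94 (SD, n = 3 lines each, adjusted p = 0.00508). Cholesterol synthesis genes were also lower, with a median of -0.32 and 10 called (adjusted p = 1.11e-13, adjusted p = 0.393 with an estimated correlation). Insig1, which restrains sterol synthesis, fell from 192 ± 24.3 to 126 ± 4.21 (adjusted p = 0.0186).

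Lists of dividing, stem and hormone cells were higher at passage 7. The median was 0.32 for the cell cycle, with 24 of 32 called (adjusted p = 4.55e-11, adjusted p = 0.309 with an estimated correlation), and 0.45 for stem cell genes, with 19 of 29 called (adjusted p = 3.19e-08, adjusted p = 0.393 with an estimated correlation). It was 0.31 for histones, with 13 of 18 called (adjusted p = 3.31e-08, adjusted p = 0.309 with an estimated correlation), and 0.56 for enteroendocrine genes, with 13 of 25 called (adjusted p = 1.19e-07, adjusted p = 0.393 with an estimated correlation). Wnt targets had a median of 0.41 with 9 of 19 called (adjusted p = 2.79e-06, adjusted p = 0.393 with an estimated correlation), tuft cell genes 0.43 with 5 of 16 (adjusted p = 0.00343, adjusted p = 0.393 with an estimated correlation) and Notch genes 0.25 with 3 of 11 (adjusted p = 0.0473, adjusted p = 0.631 with an estimated correlation). With fry 8 lists passed between passages, among them the cell cycle (0.0073) and enterocyte (0.0162) lists, and the cholesterol (0.078), Wnt target (0.0611) and Notch (0.086) lists did not. Myc, a transcription factor of growth, rose from 33.5 ± 2.51 to 53.1 ± 1.74 (adjusted p = 0.0186), and Cck, the hormone cholecystokinin, from 23.6 ± 4.05 to 41.2 ± 9.63 (adjusted p = 0.0203). The mitochondrially encoded share of the summed RPKM was 10.83%, 11.18% and 10.67% at passage 5 and 13.03%, 12.58% and 12.17% at passage 7, in GFP, clone 1 and clone 3.

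The passages differed in 1975 genes in a fit with the line as a term, and PLAGL2 and GFP in 1 in a fit that leaves passage and clone in the spread, where the same terms gave 342 genes for clone 3 against GFP and 12 for clone 1. With every library thinned to the smallest total 1353 genes passed (1328 to 1400 over the draws), 692 higher and 661 lower. After a correction for GC content 1482 passed, 510 higher and 972 lower against 1111 and 864 without it, and the median of the enterocyte list was -1.07, so neither depth nor GC content alone accounts for the pattern, while the number of higher genes fell with both. Among the 10 splits of the libraries into 3 and 3, the real split alone, 1 of 10, gave as many genes, and the highest other gave 0. However, 10 splits are too few to reach 0.05, and only 4 of them part the libraries of all 3 lines. Every split but the real one also leaves the passage difference in the spread, so few genes could pass there. The splits therefore do not decide the question. Since all libraries of a passage share a letter, passage could not be separated from the day of culture or of library preparation, and no biological explanation was tested.

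Imprinted genes were examined because H19 and Cdkn1c rose in clone 3, where Igf2, an imprinted growth factor gene beside H19, was at a mean of 0.992 against 0.184 in GFP (adjusted p = 0.175). A joint rise of imprinted genes was not found. The 20 tested imprinted genes other than H19, Igf2, Cdkn1c and Ascl2 had a median log2 change of 0 in clone 3, with 10 higher, 10 lower and 0 called, and the camera test of them pointed down.

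Of the 57 genes called in clone 3 against GFP, 53 had a clone 1 mean between those of GFP and clone 3, and the median clone 1 change was 0.46 of the clone 3 change. In 100 simulations with those 57 genes changed in clone 3 and none in clone 1, the share in between was 54% on average and 75.9% at most, against 93% observed, and the ratio was at most 0.04. A first simulation, in which all genes were changed, gave 65% on average and 69.3% at most, and the other was made after its result was seen. Both drew the noise of each gene independently, whereas real genes can move together, so the simulated maxima may be too low. The distance of the observed share from them is therefore not a measure of significance. These values are consistent with clone 1 carrying a smaller form of the change of clone 3, but the clones share their GFP controls and PLAGL2 level cannot be separated from clone.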
